A study of Mus musculus with 2 samples.

How the data were processed

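H3K4me1 ChIP-seq peaks of limbs at embryonic day 10.5 were analysed for 2 biological replicates of 1 group, with pools of 69 and 51 embryos. The authors deposited 1 peak list per replicate, 1 list called on both replicates together and 1 replicated list, which per the deposited notes derives from the other 3. Per the labels, positions are on mm10. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here. Per the deposited notes, the list of replicate 1 was made from its alignments and 2 other files, and that of replicate 2 from its alignments and 1 other file. Each peak carries the authors' enrichment value, which was read as a fold (ratio) over control because the deposited file type defines no further unit and all values exceed 1. It was used to describe and rank peaks within a list and to correlate paired peaks between the replicates. The authors also deposited the −log10 of a p-value and of a q-value per peak, and no −log10 p was below 2. The files hold no read counts, so the depth is unknown and no interval that needs it is given.

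Peaks on chromosomes 1 to 19, X and Y were used, which left out 2 peaks of the pooled list, 2 of replicate 2 and 1 of the replicated list. Genes were protein-coding genes of the GENCODE M21 annotation and sequence was the GRCm38 genome, the same build as mm10, with the TSS at the 5′ end of each gene and 21728 genes outside Y. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.

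Overlap meant at least 50% of a peak's length in the other list, compared with 100 circular shifts of a list along each chromosome. Coverage near a gene was the percent of bases within 50 kb of its TSS in peaks. The median of each list was ranked among those of 10000 random lists with the same make-up by 5 classes of gene density, and was called outside the range above the 97.5th or below the 2.5th percentile. No p-value was computed for it because genes are not replicates. The 15 lists covered limb patterning transcription factors, limb signalling, limb ectoderm and apical ridge, cartilage, myogenic, endothelial, erythroid, macrophage and other white blood cells, neural crest and Schwann cells, neurons and neural tube, heart, liver, ubiquitous genes, olfactory receptors, and spermatid and oocyte. Domains were peaks joined across gaps of up to 3 kb. The profile at the TSS used bins of 100 bp. Consensus sequences were sought in 500 bp at summits over 5 kb from a TSS and in windows 5 kb to either side outside every peak, reweighted to the same GC content in bins of 2%, with a jackknife over chromosomes. Gene lists, sequences, the tests of each comparison and most alternatives were fixed before the data were examined, and later ones are named with the additional observations.

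Genes were named by a rule fixed in advance: those at the 10 domains with the most bases in peaks, a fixed set of 26 limb and marker genes, the 2 highest and 2 lowest members of each list (the lowest olfactory receptors tie at 0), and the 5 strongest and 5 widest replicated peaks. The replicates were compared by overlap, by the correlation of fold enrichment and by the difference in coverage near each gene list, ranked among random lists in the same way. An SD between replicates is from 2 values. Alternatives were the pooled list, a −log10 q of at least 2, each replicate alone, other overlaps, windows, gaps, promoter distances and TSSs, equal numbers of peaks, other matching of random lists, and motif windows of 200 bp or without GC reweighting.

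The code was tested on simulated data. Of 100 random lists of 20 genes among 21728 with no change, 4 were called. With coverage raised 1.5-fold, 26% of 50 lists were called, with 2-fold 60% and with 3-fold 90%, so that a list inside the range is not shown to have ordinary coverage. Planted overlap of 59.9% of peaks was recovered as 60.8%, and a planted motif ratio of 1.62 as 1.56.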

Results

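H3K4me1, the monomethylated form of lysine at position 4 of histone H3, was mapped in mouse limbs at embryonic day 10.5 by ChIP-seq, in which chromatin is precipitated with an antibody and its DNA is sequenced. The mark is known from enhancers and from the flanks of active promoters, and the limbs are small buds of mesenchyme under ectoderm at this stage. There was 1 group with 2 biological replicates, pools of limbs from 69 embryos (replicate 1) and 51 embryos (replicate 2) of both sexes. Each replicate had its own peak list, with 223561 peaks over 125 Mb in replicate 1 and 205072 peaks over 146 Mb in replicate 2. A pooled list of the whole series held 228576 peaks and a replicated list, drawn from it, held 149610 peaks over 165 Mb, which is 6.23% of the called bases of the genome. This is more than either replicate covered, and 98.4 Mb lay in peaks of both replicates. Coverage in the replicated list is thus not the share of bases found in both. The depth is unknown, because the files hold peaks and no read counts. The design has no second condition, so the comparisons are between gene groups and regions, between peaks and chance positions, and between the replicates. Values of single genes and lists are from the replicated list unless a replicate is named, and replicate means are given with their SD (n = 2).

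Transcription factors that pattern the limb had the highest H3K4me1 coverage of the 15 fixed gene lists. Within 50 kb of the transcription start site (TSS), a median of 35.8% of bases lay in peaks over the 40 factors, and 30.2% ± 1.42 (SD, n = 2) in the lists of the separate replicates. The median of all 21728 protein-coding genes was 6.52%. All 40 factors were above that median and 29 were among the top 10% of genes. No median of 10000 random lists matched on gene density was as high (95% of them lay between 3.41% and 10.3%). Hoxd9 (77.2%) and Hoxd10 (74.4%), genes of the cluster that patterns the limb axis, were the highest members, and Etv5 (13.4%) and Irx5 (15.6%) the lowest.

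Lmx1b, which specifies dorsal limb, lies on chromosome 2 at 33560965 to 33640511 (mm10) and had 64.8% of its window in peaks (60.4% ± 1.03). Hoxa11 had 56.3% (49.7% ± 5.10), Hoxd13 had 53.6% (45.1% ± 5.12) and Hoxa13 had 44.8% (38.3% ± 5.36). Tbx4, a hindlimb gene on chromosome 11 at 85886422 to 85916097, had 55.4%, with 42.3% in replicate 1 and 51.8% in replicate 2. Tbx5, its forelimb counterpart on chromosome 5 at 119832668 to 119885219, had 34.2%, with 29.3% and 27.3%. Pitx1, another hindlimb gene, had 24.2% (19.7% ± 2.38). Hand2, an upstream regulator of Shh in the limb, had 39.3% (32.6% ± 4.21), and Gli3, a mediator of hedgehog signalling, had 23.7% (19.5% ± 2.24). The mesenchymal factors Prrx1, Msx1 and Meis1 had 32.2%, 34.6% and 28.3%. The strongest peak within 50 kb of the Lmx1b TSS was intronic, 13601 bp wide and 9.21-fold enriched, and that of Tbx4 was in its intron on chromosome 11 at 85893420 to 85897199 with 7.93-fold.

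Limb signalling genes also had higher coverage than random lists. Their median was 19.4% over 33 genes (16.9% ± 1.73 in the replicates), above all 10000 random lists, and 30 members exceeded the median of all genes. Bmp7 (45.8%) and Spry4 (41.1%) were highest, and Fst (4.75%) and Wnt7a (5.49%) lowest. Fgf8, the growth factor of the apical ridge, had 22.8%, and Fgf10, its mesenchymal partner, had 15.4%. Shh, the signal of the posterior limb margin, had only 8.75% (6.86% ± 0.375) and Grem1, a BMP antagonist, 8.41% (6.26% ± 0.571). The strongest peak near Shh was in its intron on chromosome 5 at 28462818 to 28465862, with 4.48-fold enrichment.

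Lmbr1, whose introns are known to hold a limb enhancer of Shh, had 1.74% of the bases within 50 kb of its TSS in peaks. That window does not reach the peaks in intron 5, whose summits lie 61890 to 66664 bp from the TSS. Over the body of Lmbr1, on chromosome 5 at 29229802 to 29378390, there were 5 replicated peaks. The widest of them, at 29313072 to 29315593 in intron 5, was 2522 bp wide with 3.91-fold enrichment. Of the bases of this Lmbr1 peak, 73.0% lay in peaks of replicate 1 and 92.9% in peaks of replicate 2.

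**Figure D1:**
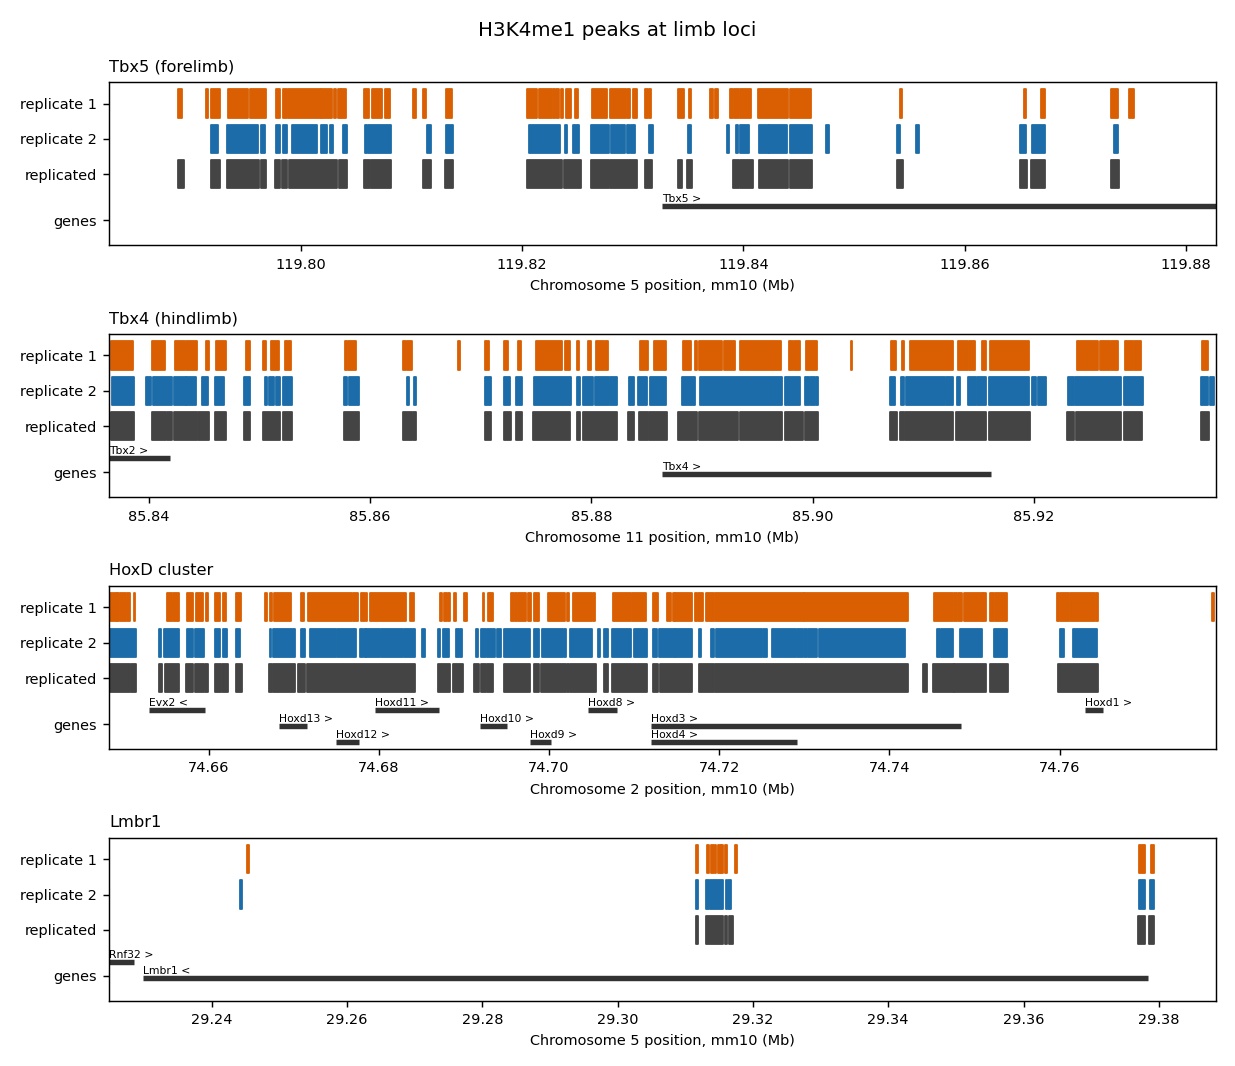
Peaks of replicate 1, replicate 2 and the replicated list along 4 regions (horizontal axes, mm10 position in Mb), with gene bodies under them and arrowheads for strand. Peaks cover most of the HoxD cluster (79.2% in the replicated list), while Lmbr1 has 5 replicated peaks over its body, mostly in intron 5.

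Genes of limb ectoderm and apical ridge had a median of 14.5% over 20 genes (percentile 99.88 among random lists; 11.1% ± 1.83 in the replicates), with Sp6 (38.4%) and Tfap2a (36.7%) highest and Krt5 (1.32%) and Trp63 (4.30%) lowest. Cartilage genes had a median of 12.5% over 18 genes (percentile 99.54; 11.4% ± 1.42 in the replicates). Runx3 (38.7%) and Pth1r (37.9%) were the highest of them and Acan (2.32%) and Snorc (2.99%) the lowest, and Sox9, the early regulator of cartilage, had 32.5%. The cartilage list was at percentile 96.36, inside the random range, when random lists were not matched on gene density. Myogenic genes had a median of 15.01% over 15 genes (percentile 99.85; 12.5% ± 2.03 in the replicates), with Chrna1 (45.3%) and Des (36.1%) highest and Met (3.06%) and Myf5 (6.64%) lowest. Pax3, a marker of migrating muscle precursors, had 18.4%, and Myod1, a later muscle factor, 8.02%.

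Endothelial genes had a median of 14.6% over 17 genes, at percentile 97.94, just above the random range (11.7% ± 1.18 in the replicates). Fli1 (55.4%) and Eng (40.4%) were highest, Emcn (1.18%) and Tek (3.27%) lowest, and Cdh5, a junction protein of vessels, had 6.16%. The endothelial call was lost with the pooled list (96.075), in the peaks of replicate 2 alone (94.73), and with windows of 10 kb (95.755) or 100 kb (93.93).

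Markers of blood, nerve, heart and liver lay within the range of random lists. Erythroid genes had a median of 5.30% over 14 genes (percentile 15.94), with Nfe2 (32.6%) and Epor (18.5%) highest and Alas2 and Hbb-bt at 0, and Gata1, the erythroid regulator, had 1.33%. Macrophage and other white blood cell genes had 10.7% over 14 genes (85.575), from 26.8% at Fcer1g and 25.5% at Cd68 to 0.426% at Mrc1 and 0 at Adgre1, and Spi1, a myeloid regulator, had 13.7%. Neural crest and Schwann cell genes had 8.83% over 10 genes (70.9), from Sox10 (21.4%) and Pmel (14.6%) to Dct (6.17%) and Plp1 (0). Gata1, Alas2 and Plp1 are X-linked. The median of 948 X-linked genes was 0, against 6.97% for autosomal genes, so these 3 low values are not particular to their lists. Genes of neurons and neural tube had 8.72% over 20 genes (91.15), from Slc17a7 (33.1%) and Rbfox3 (24.8%) to Myt1l (1.61%) and Slc17a6 (1.38%), and Neurod1, a neuronal factor, had 7.18%. Heart genes had 10.4% over 15 genes (93.35), from Hand1 (28.5%) and Myl7 (22.3%) to Ryr2 (3.48%) and Actn2 (1.73%), and Nkx2-5, a heart factor, had 10.4%. Liver genes had 4.15% over 19 genes (14.57), from Foxa3 (16.0%) and Hnf1a (14.1%) to Cyp7a1 and Serpina1a at 0, and Alb, which encodes serum albumin, had 2.42%. With windows of 10 kb the neuron and heart lists passed the upper bound (97.86 and 98.28), and with 100 kb the heart list did (99.51).

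Genes used in most cells had a median of 12.3% over 20 genes (percentile 90.465), with Hsp90ab1 (36.4%) and Rplp0 (33.5%) highest and the X-linked genes Hprt (2.65%) and Pgk1 (1.75%) lowest. This list was above random lists with windows of 10 kb (99.64) and 100 kb (99.08). Spermatid and oocyte genes had 13.0% over 12 genes (90.905), from Prm1 (30.2%) and Tnp2 (28.2%) to Spaca1 (1.03%) and Oosp1 (0). Olfactory receptor genes, known mainly from sensory neurons, had a median of 0 over 1092 genes, below all random lists. Of them, 906 were at 0, with Olfr221 (14.5%) and Olfr155 (13.0%) highest. Of the 15 lists, 6 were above and 1 was below the range of random lists.

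Some of the lower values of single genes depended on the replicate. In replicate 1 and replicate 2, Gata1 had 0.415% and 1.28% (0.848% ± 0.612, SD, n = 2), Alb 0.760% and 1.99% (1.38% ± 0.870), Hprt 0.440% and 2.81%, and Pgk1 0.803% and 1.68%. Ryr2 had 1.51% and 3.31%, Etv5 7.93% and 12.6%, Fst 2.95% and 4.40%, Tek 2.18% and 2.91%, and Spaca1 0.666% and 0.877%. Met had 2.32% and 4.51%. Other low values came from the choice of list. Krt5 (1.00% and 0.786%), Myf5 (4.12% and 5.41%) and Fgf10 (10.02% and 11.97%) were below their replicated values in both replicates. The lower replicate value of each was over 1.5 times below the replicated one. The median of all genes was lower in both replicates too (4.71% and 5.65%, against 6.52% in the replicated list). Adgre1 and Plp1, at 0 in the replicated list, had 0.332% in replicate 2 and 0.205% in replicate 1.

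Peaks were joined across short gaps into domains, which were ranked by their bases in peaks. The domain with the most bases in peaks lay over Gse1 on chromosome 8 at 120249695 to 120576950, with 288 kb in peaks (264 kb in replicate 1 and 271 kb in replicate 2). Prdm16 on chromosome 4 followed with 120 kb at 154468743 to 154605678, and a domain nearest to Foxl1 on chromosome 8 at 121240485 to 121384036, inside the long gene model Gm20388, with 102 kb. The next were at Shb (91.2 kb), Hoxb2 to Hoxb9 (91.2 kb), Sept9 (89.1 kb), Ssbp3 (88.3 kb), Ski and Morn1 (86.8 kb), Igfbp4, Tns4 and Ccr7 (85.7 kb), and Hoxc4 to Hoxc12 (85.4 kb). The Hoxb domain had 86.2 kb in peaks of replicate 1 and 75.7 kb in replicate 2, and the Hoxc domain 66.4 kb and 78.4 kb. In all, 74364 domains were formed and 429 held at least 20 kb in peaks. The ranking depended on the list and on how peaks were joined: of the 10 domains, 5 were among the top 10 of the pooled list, 7 in replicate 2 and 6 in replicate 1, and 3 or 4 with other gaps.

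The strongest single peak was in an intron of Iffo2 on chromosome 4 at 139589225 to 139603465, with 13.7-fold enrichment. A peak in an intron of Rara, the retinoic acid receptor alpha gene, had 12.8-fold enrichment on chromosome 11 at 98958841 to 98971842. The peak at Hoxa3 had 12.4-fold, and a pair of Gse1 peaks 12.3-fold and 12.2-fold. The widest peak, 29846 bp, was in an intron of Igsf3 on chromosome 3 at 101378097 to 101407942, followed by peaks at Hoxb4 (27338 bp), Ahdc1 (23667 bp), Gse1 (23377 bp) and Hoxd3 and Hoxd4 (22598 bp).

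Most H3K4me1 peaks lay in introns and between genes, while promoters held more than chance. Of replicated summits, 13256 (8.86%) were within 1 kb of a TSS, against 1.68% on average (at most 1.87%) over 100 shifts of the list along the chromosomes, a 5.28-fold excess. Introns held 45.5% (37.0% after shifts), exons 5.69% (3.52%) and intergenic sequence 39.9% (57.8%). The median distance to the nearest TSS was 38726 bp, and 44.3% of summits were over 50 kb from a TSS (57.2% after shifts). The promoter share was 8.11% ± 0.143 in the replicates, and 13.9% of replicated summits lay within 2 kb of a TSS.

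Coverage was highest downstream of the TSS, with a smaller maximum upstream. Across 21728 genes, 32.5% of bases at the TSS lay in peaks, against 36.0% at 350 bp upstream and 44.6% at 950 bp downstream. The ratio of the TSS to its highest flank was 0.729, and 0.698 ± 0.0466 (SD, n = 2) in the replicates. This ratio is below 1 for any profile that peaks away from the TSS, so it is no test of a dip. The ratio of the TSS to the highest upstream bin, computed after the profile was seen, was 0.903. It was 0.966 in replicate 1 and 0.866 in replicate 2 (0.916 ± 0.0704). Averaged over all genes, a dip on that side was thus small and varied between the replicates. Single lists differed from this average. The 20 ubiquitous genes had 55.7% at 950 bp upstream and 25% at 50 bp on either side of the TSS. Downstream they had 13.75% at 550 bp and 64.35% at 1650 bp. The limb patterning factors had 68.2% at 50 bp upstream, 86.4% at 650 bp upstream and 48.4% at 3450 bp upstream.

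**Figure D2:**
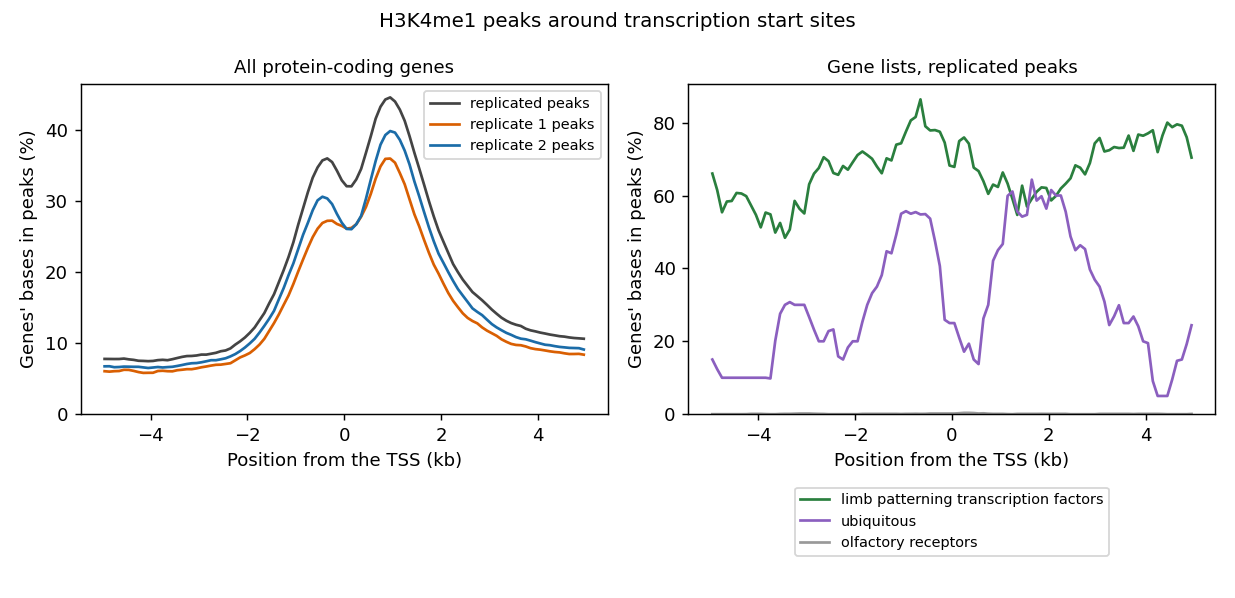
Share of bases in peaks (vertical axis, percent) against position from the TSS (horizontal axis, kb, downstream to the right), for all protein-coding genes in 3 peak lists and for 3 gene lists in the replicated list. All 3 profiles of the left panel are lower at the TSS than 950 bp downstream of it, and the olfactory receptors lie near 0.

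Homeodomain and GLI sequences were more frequent at distal peaks than in nearby windows outside peaks when these were matched on GC content. The sequence TAATTA, bound by many homeodomain proteins, was in 14.0% of 119668 distal peaks and in 7.30% of windows of the same GC content, a log2 ratio of 0.94 ± 0.02 (jackknife SE over chromosomes). The GLI sequence was rare, in 0.754% of distal peaks and 0.464% of matched windows, with a log2 ratio of 0.70 ± 0.11. The PBX-HOX sequences gave a ratio of 1.62, the GLI sequence 1.62, the posterior HOX sequences 1.35, LEF/TCF 1.29, TEAD 1.13 and the TWIST type E box 1.11. The 95% intervals of these 7 of 10 sequences lay above no difference. AP-1 (1.03) and HNF4 (0.941) had intervals that included it, and GATA (0.942) was lower. Peaks were richer in GC (49.2%) than nearby windows (43.7%), and 4 of the 7 calls rest on the matching: without it TAATTA had a ratio of 1.00, PBX-HOX 1.03, posterior HOX 0.892 and LEF/TCF 0.984. GLI (2.30), TWIST (1.18) and TEAD (1.15) stayed higher without it, and AP-1 (1.08) became so. The GATA call was lost in windows of 200 bp (0.952) and in the peaks of replicate 1 (1.00), and AP-1 was higher in those of replicate 2 (1.04).

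**Figure D3:**
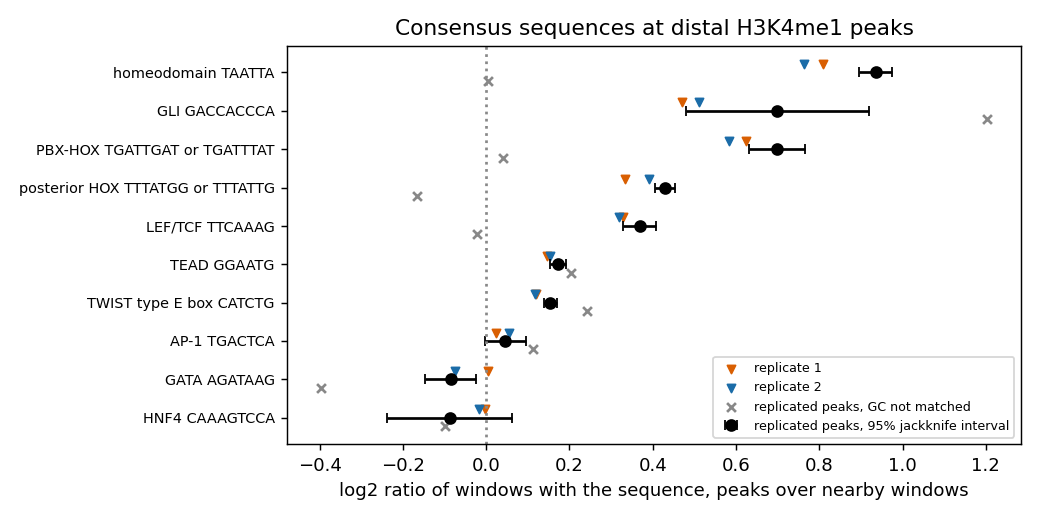
Log2 ratio of the share of windows with each consensus sequence, distal peaks over nearby windows (horizontal axis), for 10 sequences. Circles with 95% jackknife intervals are replicated peaks matched on GC content, triangles are the replicates and crosses are replicated peaks without GC matching, which for TAATTA move from 0.94 to near 0.

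Coverage of the X chromosome was far below that of every autosome. In the replicated list 0.678% of its called bases were in peaks, against an autosomal median of 6.69% (5.22% on chromosome 3 to 10.7% on chromosome 11), a ratio of 0.101. The ratio was 0.0750 in replicate 1 and 0.107 in replicate 2. A peak lay within 1 kb of the TSS of 190 of 948 X-linked genes (20.0%) and of 14031 of 20780 autosomal genes (67.5%). No peak was listed on the Y chromosome.

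**Figure D4:**
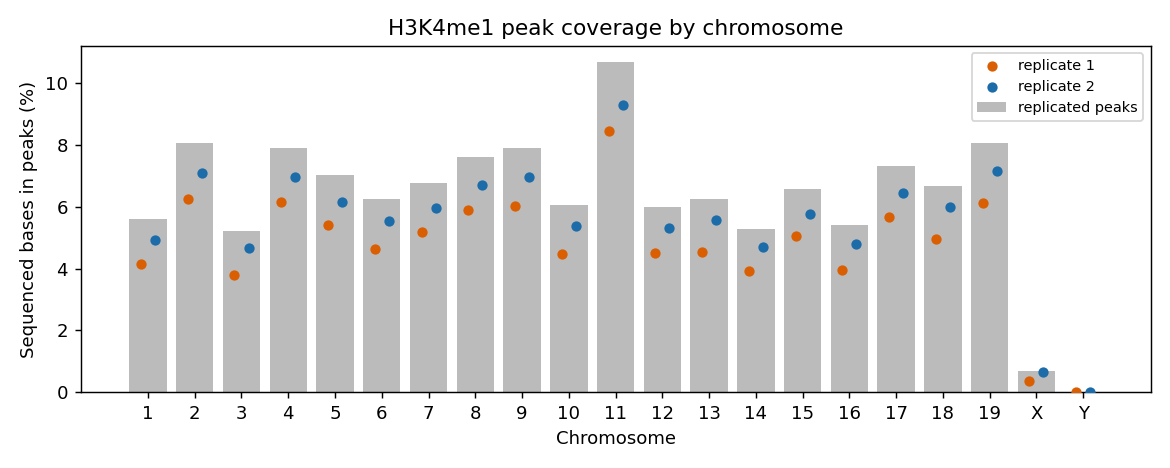
Share of called bases in peaks (vertical axis, percent) on each chromosome (horizontal axis). Bars are the replicated list and points the replicates. The X chromosome has 0.678%, and the autosomes 5.22% to 10.7%.

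The replicates shared most of their strong peaks and fewer of their weak ones. Of replicate 1 peaks, 68.3% had at least 50% of their length in replicate 2 peaks (at most 6.32% over 100 shifts), and 57.6% of replicate 2 peaks were so covered by replicate 1 (at most 5.19%). When 50% of both peaks had to overlap, the shares were 41.4% and 45.1%. The Jaccard index of covered bases was 0.572, against at most 0.0313 after shifts. Over 10 equal classes of fold enrichment, sharing went from 41.5% in the lowest class to 99.7% in the highest for replicate 1, and from 32.6% to 98.5% for replicate 2. Each replicate 1 peak with at least 50% of its length in a replicate 2 peak was paired with it. A wide replicate 2 peak can therefore occur in several pairs. Across 149171 paired peaks, which are not independent replicates, fold enrichments had a Spearman correlation of 0.524 and a Pearson correlation of 0.563 on log2 values. Across genes, coverage within 50 kb had a Spearman correlation of 0.988.

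Near genes of limb patterning and signalling, peaks covered more bases in replicate 2 than in replicate 1. The median difference, replicate 1 minus replicate 2, was -2.70 percentage points for the patterning factors (31 of 40 lower in replicate 1), -1.80 for signalling (28 of 33) and -2.64 for ectoderm and ridge (16 of 20). That of all genes was -0.45, with 13929 of 21728 genes lower in replicate 1, 4619 higher and 3180 equal, so a majority of lower members is not particular to these lists. These 3 lists were below the range of random lists matched on gene density and of lists matched on coverage (percentiles 0, 1.72 and 0.01). The call of the patterning factors rested on neighbouring members: with 1 gene of each run of neighbours their median was -1.69, at percentile 7.8 of lists matched on coverage and within the range. In that setting the signalling genes (1.72) and the ectoderm and ridge genes (0.2) were below it. With windows of 10 kb and lists matched on coverage, the signalling genes (17.48) and the ectoderm and ridge genes (49.145) were within the range, and the patterning factors (1.17) below it. The ectoderm and ridge genes were also within the range of lists matched on gene density with equal numbers of peaks per replicate (6.44) and with windows of 10 kb (10.63). The cartilage list (-1.43) was below the range when lists were matched on gene density (1.31) and within it when matched on coverage (9.63).

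Other lists passed the bounds in some settings. With windows of 10 kb and lists matched on gene density, the ubiquitous genes (-2.59 percentage points, percentile 0.31) were below the range and the endothelial genes (0.115, percentile 99.245) above it, while with 50 kb both were within it (59.16 and 27.2). With lists matched on coverage, neither was outside it at 10 kb (7.56 and 96.2). The myogenic genes, at percentile 5.6, were below the range with equal numbers of peaks (0.36), with windows of 10 kb (2.16) and at a −log10 q of at least 2 (2.36). Against lists matched on coverage they were within it (23.845), also with windows of 10 kb (20.805) and with 1 gene of each run of neighbours (26.17). The heart genes (53.27) were above it with 1 gene of each run of neighbours and lists matched on coverage (98.83). The olfactory receptors had medians of 0 in both replicates and a median difference of 0, which lay above random lists (100) because those were below 0, and within the range of lists matched on coverage (50). Per the deposited notes, the replicates' lists were made with different numbers of other files, so differences between replicates include any from processing.

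The replicated list kept 65.5% of the pooled peaks and left out 78966. Kept peaks had a median fold of 3.08 and a median width of 775.5 bp, against 2.11 and 273 bp for those left out. The share kept went from 12.9% in the lowest of 10 classes of fold enrichment to 100% in the highest. All 91497 pooled peaks with at least 50% of their length in peaks of each replicate were kept, which is 40.03% of the pooled list. The other 58113 replicated peaks (38.8%) were so covered in 1 replicate or in none. Of the replicated peaks, 26901 (18.0%) did not share 50% of either peak with a peak of each replicate, and the authors' rule for a replicated peak is not given in the sources used here.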

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

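Random lists matched on coverage (alone, with windows of 10 kb or with 1 gene of each run of neighbouring members), replicates alone for the motifs and autosomal genes only were chosen after the results were seen. The overlap of replicate 1 peaks with replicate 2 was 75.3% with 1 base, 41.4% with 50% of both peaks, 69.4% at a −log10 q of at least 2 and 76.6% with equal numbers of peaks, and that of replicate 2 with replicate 1 was 70.6%, 45.1%, 58.3% and 61.7%. The Spearman correlation of fold enrichment was 0.505 with 1 base and 0.569 for −log10 p. The share of pooled peaks kept was 70.4% at the stricter q, and 40.03% or 54.1% when overlap of 50% or 1 base with each replicate replaced the authors' list. The promoter share was 7.17% in the pooled list, 13.9% within 2 kb, 12.1% with every transcript's TSS and 8.01% to 8.21% without a replicate. The TSS ratio was 0.779 in the pooled list and 0.665 to 0.731 without a replicate. Of the 10 domains with the most bases in peaks, 5 stayed among the top 10 in the pooled list, 4 with a gap of 1 kb, 3 with the widest gap and 6 to 7 without a replicate. The X ratio was 0.0750 to 0.107 without a replicate. Lists outside the random range for the replicate difference, one of them the olfactory receptors at 0, went from 5 to 3 when matched on coverage, to 1 with windows of 10 kb as well and to 3 with 1 gene of each run as well. With windows of 10 kb alone, the ubiquitous (0.31) and endothelial (99.245) lists left the range on the other side of its middle. Without GC reweighting 4 sequences were higher in place of 7, and the log2 ratios of posterior HOX (-0.17) and LEF/TCF (-0.0229) turned negative, since peaks are richer in GC. That of GATA was -0.0756 without replicate 1 and turned to 0.00484 without replicate 2. For the others the cause was not tested. Of 135 other list percentiles, 125 kept their call, 5 lost it and 5 gained it, and of 90 percentiles of the replicate difference 72 kept it, 12 lost it, 4 gained it and 2 did so on the other side. Leaving out X-linked genes changed no list's call. No paired analysis was possible because there is 1 group. Unknown depth limits what an absent peak shows.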

Other observations

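The gene families, the Hox clusters, all 3 tests of X copy number, the forelimb and hindlimb test and the transcription factor and replicate tests with 1 gene of each run of neighbours were chosen after results were seen. The list percentile with 1 gene of each run was chosen before, and its reading as a test after. Hox genes had the highest median coverage of 16 families, 69.2% over 39 genes, all above the median of all genes and 37 in the top 10%. These genes lie in the HoxA, HoxB, HoxC and HoxD clusters, so neighbours share peaks within their windows and are not independent loci. No family was reduced to 1 gene of each run of neighbours, so calls of families with neighbouring members are descriptive. Peaks covered 79.2% of the HoxD cluster (67.9% ± 0.621 in the replicates, SD, n = 2), 77.0% of HoxA (70.9% ± 2.06), 69.7% of HoxC (59.0% ± 7.44) and 57.2% of HoxB (50.6% ± 5.14). HoxC had more in replicate 2 (64.2%) than in replicate 1 (53.7%), and HoxB less (47.0% and 54.3%). Within HoxA, the 2.5 kb on either side of the Hoxa9 TSS had 0% in the replicated list, 6.74% in replicate 1 and 0 in replicate 2, while Hoxa6 had 100%, 90.4% and 100%. That Hoxa9 TSS is the 5′ end of a gene model at 52223100 to 52231089, next to Hoxa10 at 52231197 to 52240854. Other possible starts of Hoxa9 were not examined. Ephrins and Eph receptors (23.5%, 22 genes), Tbx genes (29.98%, 13 genes), Wnt genes (20.9%, 19 genes), Sox genes (16.7%, 19 genes), Sp and Klf genes (13.9%, 26 genes), ribosomal protein genes (13.1%, 72 genes), Fox genes (11.99%, 44 genes), Fgf genes (11.7%, 22 genes) and collagens (9.69%, 44 genes) were also above random lists. Irx (13.5%), Bmp (6.90%), frizzled (12.05%) and keratin genes (6.43%) lay inside the range, and vomeronasal receptors (288 of 326 at 0) and defensins (38 of 64 at 0) below it.

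The high coverage near limb patterning factors was compared with that near 23 transcription factors of the neural, neural crest, heart and liver lists. Factors of the myogenic, endothelial, erythroid and white blood cell lists were left out. Among those left out, Fli1 had 55.4%, Nfe2 32.6%, Myf5 6.64% and Gata1 1.33%. The median of the 23 was 10.4% against 35.8% for the limb factors (two-sided permutation p = 1e-05, the smallest that 100000 resamples give). Genes are not replicates and neighbours share peaks, so this p describes these lists only. With 1 gene of each run of neighbours, 32 limb factors had a median of 30.9% against 10.4% (permutation p = 1e-05), and the limb list stayed at percentile 100.

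The X chromosome had low coverage in both replicates. Its repeats, GC content and gene density may account for part of this. Against autosomal windows of 100 kb matched on them, its ratio was 0.348 in place of 0.101. The lowest autosome had 0.840, so this matching did not account for all of the low coverage. Windows were matched in broad classes, and those of X averaged 46.4% repeats against 30.6% to 35.8% on the autosomes. X windows may hold more repeats than their matches, so a larger part from repeats is not excluded. A lower copy number in embryos of both sexes stays open: going from the pooled libraries to a single library left at least 0.664 of the median autosomal coverage and 0.606 in windows matched to X, but on X itself only 0.458 in replicate 1 (0.771 in replicate 2). Library depths are unknown, so the share of reads that a single library lacks cannot be set against that of a missing copy. A lower level of the mark on an X chromosome, as on an inactive X, is open too, and no biological explanation was tested because the sexes were pooled.

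The limb lists had more bases in peaks in replicate 2 than in replicate 1. Wider calls in replicate 2 wherever coverage is high stay a candidate explanation. Against lists matched on coverage, the signalling and ectoderm lists were at percentiles 1.72 and 0.01. With 1 gene of each run of neighbours they were at 1.72 and 0.2, and all of these values go against wider calls. With windows of 10 kb, however, signalling (17.48) and ectoderm (49.145) were within the range. The patterning list was at 0, at 1.17 with windows of 10 kb and at 7.8 with 1 gene of each run. For that list the matching was coarse. The highest of 20 coverage classes takes in genes of widely different coverage, and many patterning factors lie in it. Its low percentiles therefore do not decide. A different mix of forelimb and hindlimb might contribute. Hoxc10 (45.3% and 61.3%), Hoxc11 (34.1% and 49.5%) and Tbx4 (42.3% and 51.8%) had more in replicate 2, though Hoxc10 and Hoxc11 are neighbours that share peaks. Pitx1 (18.1% and 21.4%) and Tbx5 (29.3% and 27.3%) were within the range of genes with like coverage, at percentiles 13.1 and 87.4. The idea came from Tbx4, Pitx1, Tbx5 and the HoxC cluster, however. Isl1, a hindlimb gene not looked at before, was at percentile 19.5 of genes with like coverage. Without Tbx4, Pitx1 and Tbx5, the only members of these genes in it, the patterning list was at percentile 0.41, but other members may differ between the limbs too, so the mix is not excluded. The notes name 2 other files for replicate 1 and 1 for replicate 2 without saying what they are, and any effect of them cannot be told apart from that of the replicates.

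The sequences more frequent at distal peaks could reflect base composition within windows other than GC content. In a sample of 29918 peaks, reordered versions of the same bases were compared with the real sequence. For TAATTA (13 reorderings), posterior HOX, GLI and PBX-HOX (50 each), 0% reached its ratio, which argues against composition as the whole cause for them. Reordered versions still had a median ratio of 1.19 for TAATTA (real 1.87) and reached 1.42 for GLI (real 1.55), so composition as part of the cause is not excluded. For TEAD 2% and for the TWIST type E box 4% reached the ratio, 1 and 2 of 50 reorderings. Their highest reordered ratios (1.16 and 1.21) exceeded the real ones (1.13 and 1.10), so this speaks only weakly against composition. For LEF/TCF 10% reached it, so composition stays a candidate explanation there. Whether homeodomain or GLI proteins bind these peaks was not tested.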
